A study of Arabidopsis thaliana with 4 samples.

How the data were processed

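Gene expression was measured in root tips of Arabidopsis thaliana seedlings grown for 4 days at 23 °C, on 2 arrays of wild type and 2 arrays of the sol2 mutant, each hybridised with biotin-labelled cRNA. The deposited values were linear probe-set intensity values, 1 per probe set and array, and GCOS is the tool that the submitters' processing notes name for them. The algorithm and scaling target were not given in the sources used here. The mean over the middle 96% of probe sets was between 500.05 and 500.06 on all 4 arrays, so the arrays had been scaled to a common level. Array medians lay between 142.7 and 160.75, and no further normalization was applied. No detection calls were used here.

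The table held 22810 probe sets, of which 64 were controls and were left out of all tests. Gene names came from the platform annotation and from the RefSeq gene table of the TAIR10.1 assembly, which also gave the order of genes along the chromosomes and served for nothing else. Of the 22746 other probe sets, 13513 (59.4%) were paired with 1 gene, 503 with several and 8730 with no gene in these tables. The last group was counted and not named. A gene was matched through its gene identifier for 13436 probe sets and through its name for 72, and 5 had no match.

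Signals were transformed as log2(signal + 18.4), where 18.4 was the 20th percentile of all values. Fold changes on this scale understate the change of genes with low signal. Probe sets whose mean log2 value was at or above the 40th percentile were tested, which left 13648. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with genotype as the only term and Benjamini-Hochberg adjustment over the tested probe sets. A probe set was called at an adjusted p under 0.05. Besides the test, probe sets were counted whose signal + 18.4 differed at least 2-fold in the same direction in each of the 4 pairs of a sol2 and a wild type array. Gene lists were tested with limma's camera (preset correlation 0.01, 1 probe set per gene, at least 4 genes per list), with an estimated correlation and fry as alternatives. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be partly technical. With 2 arrays per genotype the precision is limited by their number.

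The groups, tests, alternatives, 29 gene lists with 505 genes and the rule for naming genes were fixed before the data were examined. The rule took every measured member of the CLV and CLE signalling list, the 12 largest rises and 12 largest falls among called probe sets, and of each other list its called members, up to 6, or otherwise the 2 members with the largest change. Because 7 unnamed probe sets ranked among the rises and 9 among the falls, both lists were continued to 12 probe sets with 1 gene, a reading of the rule chosen after the values were seen. Only 73 of the 505 listed genes had a named probe set, so most lists were thinly measured.

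No probe set was paired with SOL2 in the tables used, so the mutated gene itself was not analysed here. RNA quality was followed by the ratio of 3' to 5' control probe sets of actin, GAPDH and ubiquitin. Background was judged from 27 control probe sets for bacterial transcripts, with a median signal of 4.35 and a highest signal of 34.1. For named genes whose mean in the dimmer genotype lay at or under that highest signal, the fold change was given as a bound, for which signals of the dimmer genotype under 34.1 were set to 34.1.

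Alternatives covered quantile normalization, equal array medians, other pseudocounts (5th and 40th percentile), no filter or a 60th-percentile filter, other prior variances, a replicate block, an adjusted p threshold of 0.10 and the omission of each array in turn. A set of 18 gene families was defined from gene symbols, locus tags and a list of peroxidases before any gene's change was computed, and the locus patterns of the organelle genes were corrected after a run in which they had matched no gene. Positions were analysed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, from 10000 random draws among the tested genes. Figures were drawn with matplotlib 3.10.9.

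The fit was tested on simulated data for the comparison of sol2 with wild type, with 13648 probe sets. It called 23% of 100 probe sets changed by 1 log2 unit and 84% of 100 changed by 2 log2 units. Of 123 simulated calls, 8 were of a list of 20 genes shifted by 1 log2 unit and 8 (6.5%) fell on unchanged probe sets. None of 20 unshifted lists was called. The simulated noise was drawn from the variance model of the fit itself, independently for each probe set and array. These rates therefore do not cover noise shared between genes or replicates, or unequal spread in the genotypes. The position test gave a permutation p of 0.0001, the smallest that 10000 draws can give, for a simulated stretch with 15 added changed genes, and 0.39 without one.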

Results

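Expression in root tips was compared between 2 arrays of wild type and 2 arrays of sol2, a mutant of SOL2 (also called CORYNE), a receptor-like kinase of CLE peptide signalling. The comparison asks how the mutation affects gene expression at the root apex. Between arrays, log2 signals of the tested probe sets correlated (across probe sets, which are not independent replicates) at r = 0.983 for the sol2 pair, 0.963 for the wild type pair, and 0.943 to 0.966 for pairs of different genotype. The median absolute log2 difference was 0.182 for the sol2 pair and 0.294 for the wild type pair. Wild type replicate 2 lay nearer to sol2 replicates 1 and 2 (0.220 and 0.189) than to wild type replicate 1. For wild type replicate 1 the differences from these sol2 arrays were 0.249 and 0.326. The 3' to 5' signal ratio of actin was 8.45 and 24.5 on the wild type arrays and 11.6 and 36.9 on the sol2 arrays of replicates 1 and 2, while a second pair of actin probe sets gave 1.81 and 2.30 in wild type and 1.72 and 2.81 in sol2. The ubiquitin ratio was 3.02 and 3.87 in wild type and lower in both replicates of sol2, at 2.46 and 2.29, and the GAPDH ratio lay between 0.971 and 1.07 on all 4 arrays.

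Several genes with very low signal in wild type had high signal in sol2. AT1G23960 rose from 8.3 ± 3.82 in wild type to 948 ± 159 in sol2 (mean ± SD, n = 2, adjusted p = 0.000216, limma). AT4G15390, an acyltransferase of the BAHD type, rose from 5.6 ± 2.69 to 616 ± 56.1 (adjusted p = 0.000216). AGL42, a MADS-box transcription factor known for expression in the quiescent centre, rose from 21.4 ± 7.42 to 252 ± 70.3 (adjusted p = 0.00486). The wild type signals of these 3 genes lay on both arrays within the range of the bacterial control probe sets, whose highest signal was 34.1. Against that signal the rises were at least 27.8-fold, 18.1-fold and 7.40-fold. Their fitted log2 differences depended on the pseudocount: that of AT1G23960 was 6.52 with the 5th and 3.52 with the 40th percentile, and with the latter AT4G15390 gave 3.01 and AGL42 1.69. Other large rises started above that range: AT2G25450, the dioxygenase GSL-OH of aliphatic glucosinolate side chains, went from 196 ± 151 to 3894 ± 135 (log2 4.40 ± 0.44, SE, adjusted p = 0.00375), and ZW9 from 380 ± 134 to 6041 ± 961 (log2 3.96 ± 0.26, adjusted p = 0.000539). The value of AT2G25450 was 5.19 without wild type replicate 1 and 3.60 without wild type replicate 2.

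The remaining 7 of the 12 largest rises among probe sets with 1 gene, ranked on the log2(signal + 18.4) scale, were AT1G62510, a lipid-transfer-type protein, AT5G62340, a pectin methylesterase inhibitor-type protein (3.32), AT1G60750, an aldo/keto reductase (3.12), AT2G43535 (2.94), AT1G62480 (2.88), AT4G02540 (2.81) and AT5G43040. The mean wild type signals of AT1G62510 and AT5G43040 lay within the control range, and their rises were at least 13.0-fold and 8.49-fold. AT1G62480 had a signal of 6295 ± 163 in sol2 and 841 ± 71.3 in wild type.

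Among the falls, the sugar transporter SWEET11, which exports sucrose for phloem loading, went from 418 ± 123 in wild type to 46.9 ± 24.0 in sol2 (log2 -2.76 ± 0.33, adjusted p = 0.00782), or -1.96 with the 40th-percentile pseudocount. The largest fall among probe sets with 1 gene was that of AT5G19100, an aspartyl protease-type protein, from 1417 ± 641 to 104 ± 31.5 (log2 -3.50 ± 0.34, adjusted p = 0.00307). The gene hemb2, for a 5-aminolevulinate dehydratase of tetrapyrrole synthesis, fell from 1175 ± 171 to 171 ± 6.15 (log2 -2.65 ± 0.21, adjusted p = 0.00138). AT1G47400, an iron-deficiency peptide of the IRON MAN family, fell from 235 ± 35.5 to 44.1 ± 31.9 (log2 -2.11 ± 0.37, adjusted p = 0.0428). AT2G25150, a spermidine acyltransferase, and the cytochrome P450 gene CYP71B23 fell by 1.74 and 1.78 on the log2 scale, both with an adjusted p of 0.0453. The others were AT2G44370 (-2.86), AT1G17300 (-2.81), AT1G29180 (-2.54), AT4G01390 (-2.18), AT5G37210 (-1.95) and AT3G60980, whose mean sol2 signal lay within the control range and whose fall was at least 4.79-fold. For SWEET11, AT1G29180, AT4G01390 and AT1G47400, 1 of the 2 sol2 arrays also lay within the control range, so their log2 differences depend on the pseudocount. Without the filter on low values only AT5G19100, AT2G44370 and hemb2 of these 12 kept their call, and the other 9 had adjusted p between 0.0645 and 0.176. The calls of CYP71B23 and AT2G25150 also ended with quantile normalization, equal array medians, the 60th-percentile filter and a prior variance without trend. That of AT1G47400 ended with quantile normalization, the 5th-percentile pseudocount and a prior variance without trend.

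**Figure D1:**
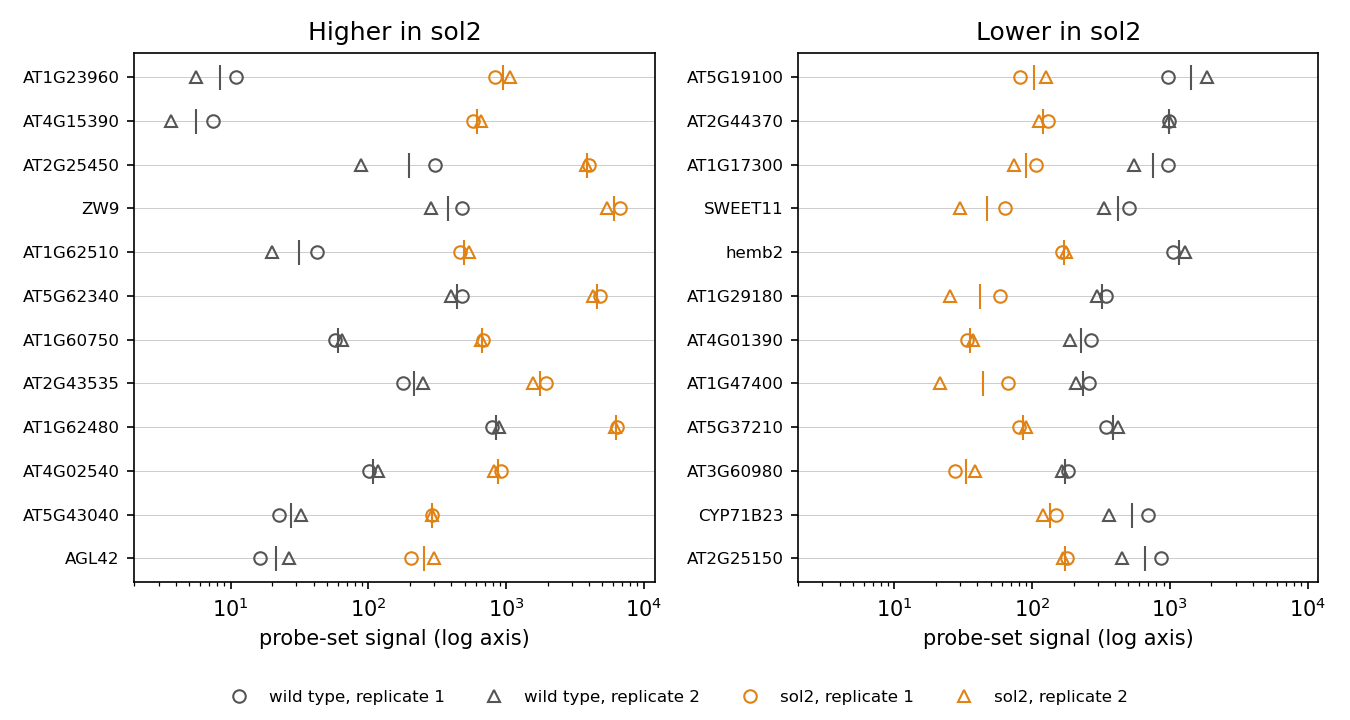
Probe-set signal (log axis) on each array for the 12 largest named rises (left) and falls (right) in sol2. Circles and triangles mark replicates 1 and 2, vertical ticks the mean of the 2 arrays of a genotype, grey wild type and orange sol2. For each gene, both sol2 arrays lie on the same side of both wild type arrays.

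In all, 129 probe sets were higher and 41 lower in sol2 at an adjusted p under 0.05, which was 1.25% of the 13648 tested. Higher signal in sol2 thus made up 75.9% of the calls, while the median log2 difference of all tested probe sets was 0.0043. That share depended on the setting. It was 58.8% with a replicate block and 87% without the filter on low values. At an unadjusted p under 0.05 (limma), 702 probe sets were higher and 513 lower. The smallest called change had a size of 0.86 on the log2 scale. Of the 170 calls, 85 belonged to probe sets with 1 gene (65 higher, 20 lower), 12 to probe sets with several genes and 73 to probe sets with no gene in the tables. A difference of at least 2-fold in signal + 18.4 in every pair of a sol2 and a wild type array was found for 179 probe sets, 139 higher and 40 lower, and 153 of these were also called. The other 2 splits of the 4 arrays into pairs gave 7 and 1. For 13 of the calls, 11 of them higher in sol2, the mean of the lower genotype was at or under 34.1. Of the 4 arrays left out in turn, those of wild type moved the counts most, to 425 higher and 144 lower without replicate 1 and to 876 higher and 549 lower without replicate 2, for which the lone wild type array was assumed to vary like the sol2 arrays. Without the filter on low values 60 were higher and 9 lower, and among the named rises the calls of AGL42 and AT2G25450 ended (adjusted p = 0.0545 and 0.0525).

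**Figure D2:**
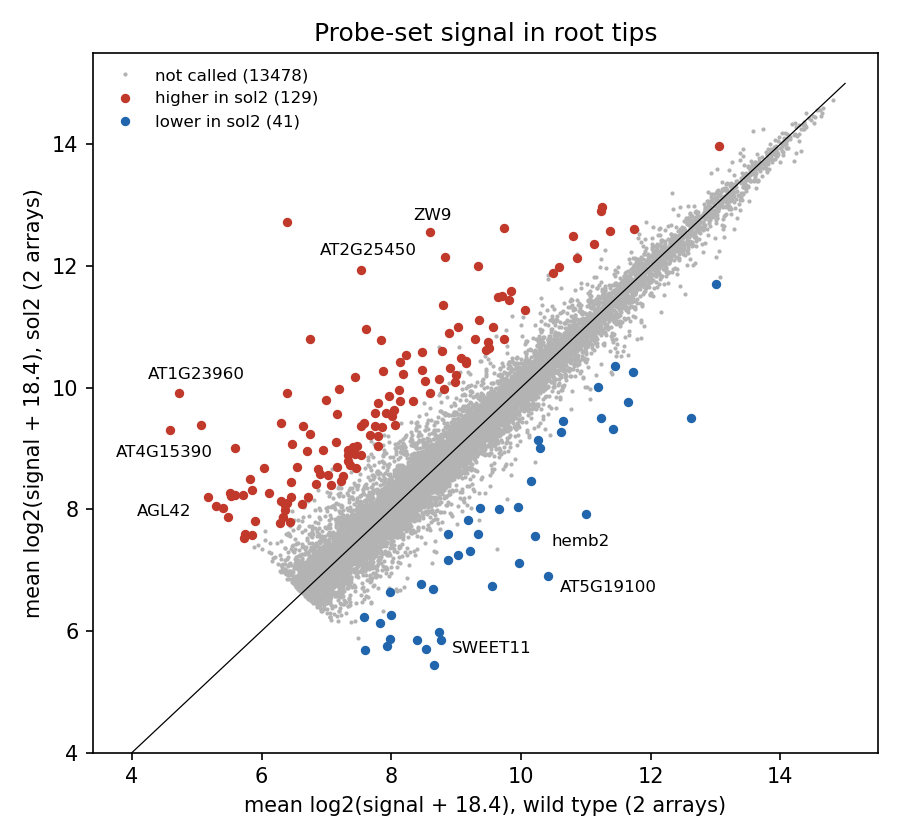
Mean log2(signal + 18.4) of each tested probe set in sol2 (vertical axis, 2 arrays) against wild type (horizontal axis, 2 arrays), with the line of equal signal. The 129 probe sets called higher are red, the 41 called lower are blue and the rest grey.

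No member of the CLV and CLE signalling list, the pathway in which SOL2 acts, passed the test, and neither of the members tested had an unadjusted p under 0.05. Of its 43 genes 10 had a named probe set, and only CLE27 and POL lay above the filter. CLE27 had a signal of 104 ± 0.636 in wild type and 70.9 ± 4.53 in sol2 (log2 -0.45 ± 0.24, adjusted p = 0.728, limma), and the phosphatase gene POL 608 ± 56.7 and 547 ± 34.0 (log2 -0.15 ± 0.20, adjusted p = 0.949). The other 8 were below the filter. Among them CLE41 had a signal of 43.4 ± 5.09 in wild type and 80.2 ± 18.9 in sol2 (log2 0.66 ± 0.28, unadjusted p = 0.0564 and adjusted p = 0.588 in the fit without a filter). ACR4 had 56.3 and 42.8, CLE44 59.6 and 46.1, CLE40 22.65 and 20.05, CLE26 15.2 and 27.7, CLE21 9.25 and 9.4, CLV3 4.05 and 3.1, and CLE46 2.95 and 2.5 in wild type and sol2, with adjusted p between 0.860 and 0.997 in that fit.

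Over all 29 fixed lists, 44 members lay above the filter. None rose and 1, SWEET11, fell. At an unadjusted p under 0.05 there were 6 of these 44, and 1215 of all 13648 tested probe sets. Adjusted over the list alone, 1 member each passed in the lists of root meristem regulators (UPB1), salicylate defence (GRXC9), flavonoid synthesis (UGT78D2), root hair markers (PRX44) and phloem markers (SWEET11). The flavonoid and phloem lists had only 1 member above the filter, so that no adjustment took place there, and the meristem and salicylate lists had 2. Nor was there any adjustment over the lists, and of these members only SWEET11 passed the main test. In 8 lists (auxin transport and synthesis, cytokinin, ethylene, brassinosteroid, jasmonate, phosphate and nitrate, epidermal patterning, endodermis and suberin) no member lay above the filter.

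On the lists of root meristem regulators, mitotic cell cycle and DNA replication, only 2 of 19, 3 of 27 and 2 of 17 genes lay above the filter, and none of these passed the test. UPB1, a transcription factor of the transition to elongation, had 806 ± 220 in wild type and 453 ± 103 in sol2 (log2 -0.80 ± 0.26, adjusted p = 0.326), and JKD 163 ± 28.6 and 165 ± 19.7. The median log2 difference of the 3 measured mitotic genes was 0.27. Of these AUR1 had 703 ± 91.1 and 948 ± 98.3 (adjusted p = 0.633) and AUR3 139 ± 2.19 and 172 ± 9.40 (adjusted p = 0.896). For DNA replication, ICU2 gave a log2 difference of 0.25 and MCM7 one of -0.03. UPB1 passed when wild type replicate 2 was left out, with a log2 difference of -1.07. The lone wild type array was then assumed to vary like the sol2 arrays.

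Among hormone and stress lists, the auxin-conjugating enzymes GH3.3 and GH3.5 had log2 differences of -0.94 ± 0.45 (adjusted p = 0.630) and -0.64 ± 0.28 (adjusted p = 0.580), and GH3.3 differed between the wild type arrays from 691 to 230. The gibberellin receptors GID1A and GID1B gave -0.45 and -0.18, COR47 -0.29, ZAT10 0.43 and ROF2 0.27. The salicylate-responsive glutaredoxin GRXC9 gave -0.75 ± 0.23 (adjusted p = 0.277) and SAG101 -0.20. For iron deficiency, F6H1 gave 0.55 and PYE -0.23. The flavonol glucosyltransferase UGT78D2 gave -0.52 ± 0.19 (adjusted p = 0.391), the glucosinolate enzyme UGT74B1 0.23 and the clock gene GI 0.29. Without wild type replicate 2, the log2 differences of GH3.5, GID1A and GRXC9 were -1.01, -0.82 and -0.92, and without wild type replicate 1 that of F6H1 was 1.02. The log2 difference of GH3.3 was -1.70 without wild type replicate 2 and -0.19 without wild type replicate 1. In those fits the lone wild type array was assumed to vary like the sol2 arrays. With a replicate block on all 4 arrays GH3.3, GH3.5, GRXC9, F6H1 and UGT78D2 passed. Nothing in the labels pairs the replicate numbers, however.

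Markers of other cell types and of scaling were measured in the same fit. The root cap gene RCPG had 401 ± 163 in wild type and 603 ± 39.5 in sol2 (log2 0.62 ± 0.29, adjusted p = 0.599). Of 4 root hair markers none passed; PRX44 gave -0.89 ± 0.26 (adjusted p = 0.238) and PRX7 0.45 ± 0.22 (adjusted p = 0.629). IRX10, the only xylem marker above the filter, gave 0.08. The 3 photosynthesis genes had a median log2 difference of -0.19, with RCA at -0.67 ± 0.23 (adjusted p = 0.372) and PSBW at -0.19. Among 6 cell wall loosening genes XTH18 gave -0.41 and EXPB1 -0.28, and among 4 reference genes FBOX gave -0.47 and UBC21 0.37, with adjusted p between 0.683 and 0.895. Camera could test only 3 lists and called none, with adjusted p of 0.915 for cell wall loosening, 0.470 for root hair markers and 0.975 for reference genes; none had an unadjusted p under 0.05 by camera, and with an estimated correlation or fry none was called either (adjusted p = 0.984 and 0.983 for each list). The median and mean of the cell wall loosening list differed in sign (0.003 and -0.03), as did those of the reference genes (0.03 and -0.01). Without wild type replicate 2, the log2 differences of RCPG and PRX44 were 1.03 and -1.29, and without wild type replicate 1 that of PRX7 was 0.72. In those fits the lone wild type array was assumed to vary like the sol2 arrays. With a replicate block on all 4 arrays RCPG, PRX44, PRX7 and RCA passed, though the labels do not pair the replicate numbers.

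The genes that differed at least 2-fold in signal + 18.4 in every pair of arrays were not spread evenly over the genome. Of 7249 tested genes with a position in the gene order, 90 met this criterion, 70 of them higher in sol2. There were 10 pairs of next-door tested genes among them, against a mean of 1.1 in 10000 random draws (permutation p = 0.0001, the smallest they can give, one-sided). On chromosome 5 a stretch of 293 tested genes, picked for its density of these genes, ran from AT5G26260 to AT5G44560 and held 16 of the 90, 14 higher and 2 lower, among them AT5G43040 and AT5G37210. The longest run without such a gene, 753 tested genes on chromosome 3 from AT3G01130 to AT3G23550, exceeded the median of 373 in random draws (permutation p = 0.0041, one-sided). None of 142 tested genes within 200 annotated genes of SOL2 met the criterion, where the draws gave a mean of 1.76. SOL2 lies on chromosome 5 as well, outside the stretch of 293 tested genes.

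**Figure D3:**
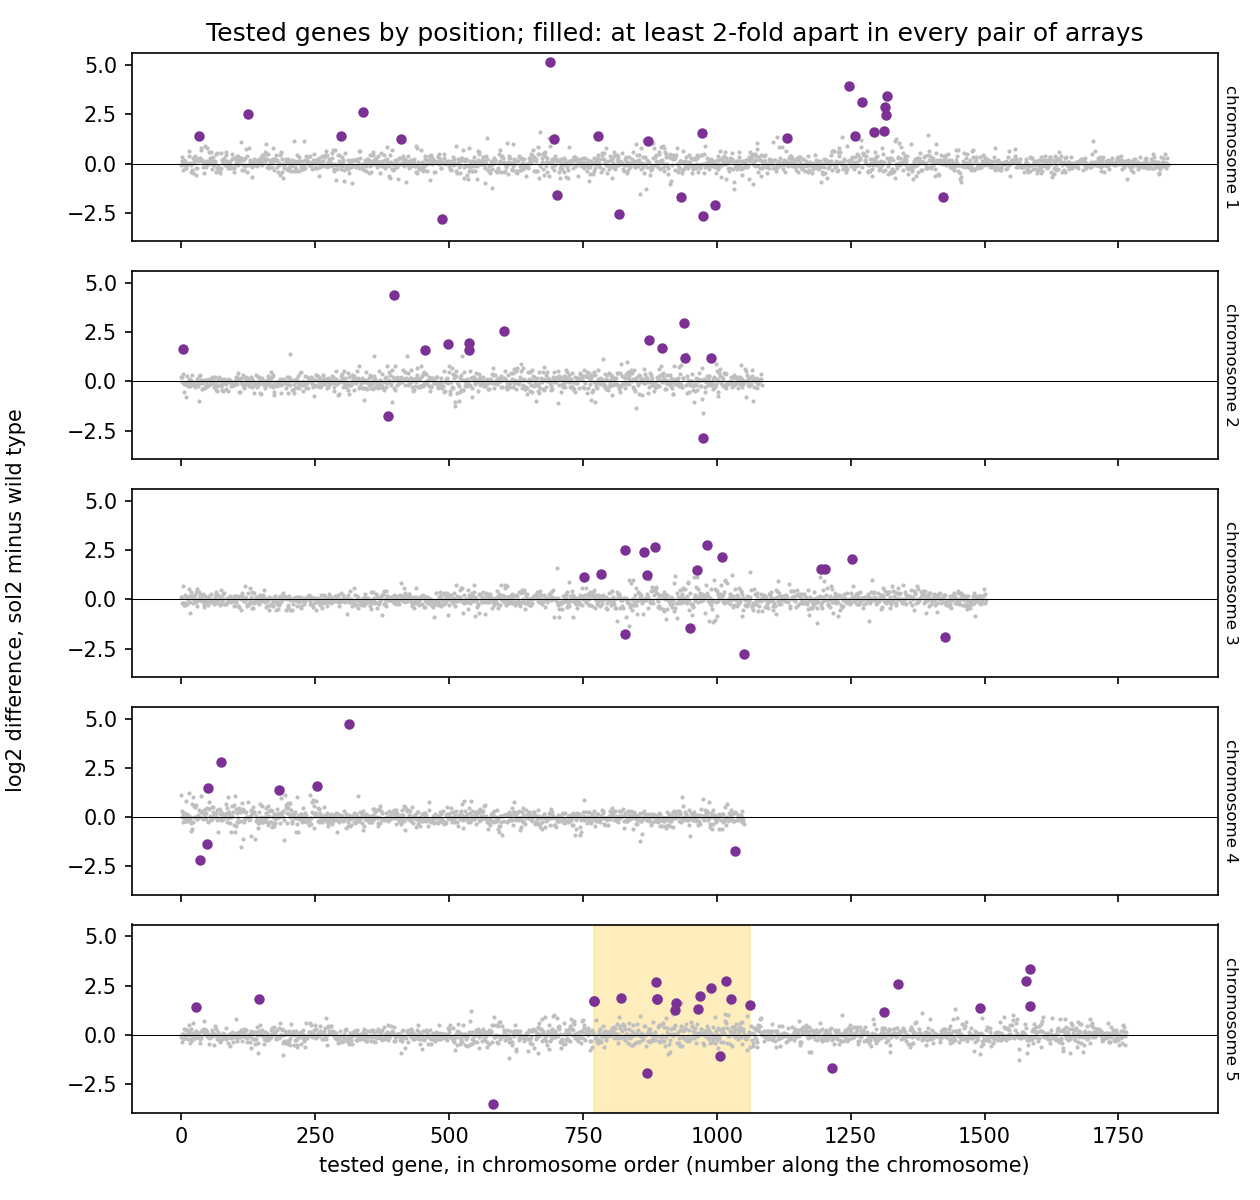
Log2 difference (sol2 minus wild type) of each tested gene, placed by its order along the 5 chromosomes. Purple points differed at least 2-fold in signal + 18.4 in every pair of arrays, grey points did not, and the yellow band marks the stretch of 293 tested genes on chromosome 5 with 16 purple points.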

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

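The gene families were added after the annotation had been seen but before any gene's change was computed, and the count without the dense stretch was added after the result was seen; the other alternatives were planned. No call of a named gene under any alternative went against its reported direction, and all 170 calls kept their direction wherever tested. Of the 24 largest changes, 13 stayed called under every alternative that tested them; 11 ended without a filter, and of these AT1G47400, CYP71B23 and AT2G25150 also under some others. Of 32 named genes not called, 12 were called under an alternative, always with the replicate block or an array left out, and 6 (JKD, MCM7, GID1B, XTH18, IRX10 and PSBW) changed sign under at least 1 without being called there, which was not counted as a reversal. Without the filter 60 probe sets were higher and 9 lower, 296 differed at least 2-fold in every pair, and 1 gene family was lower; with the 60th-percentile filter the counts were 68, 15 and 95. These filters change the number of probe sets tested and also the prior variances estimated from them, so unadjusted p-values moved too. The 2-fold count, taken on signal plus the pseudocount, was 191 with the 5th-percentile pseudocount and 127 with the 40th. With the 40th-percentile pseudocount the log2 differences of AT1G60750, SWEET11, AT1G29180, AT4G01390 and AT1G47400 were 2.41, -1.96, -1.72, -1.40 and -1.36. At an adjusted p under 0.10, 199 were higher and 78 lower. With arrays left out in turn, higher counts ranged from 107 to 876 and lower counts from 46 to 549, each highest without wild type replicate 2; fixed lists called lower ranged from 0 to 2, families higher from 0 to 1 and families lower from 1 to 5. In such fits the genotype left with 1 array was assumed to vary like the other. The median absolute log2 difference was 0.294 between the wild type arrays and 0.182 between the sol2 arrays. Whether this accounts for the counts with an array left out was not tested. The 2-fold counts were 225 to 449 then, but with 2 pairs instead of 4 the criterion is easier to meet, so their rise says nothing about the arrays. Nothing in the labels pairs the replicate numbers. The differences between replicates 1 and 2 correlated at 0.441 between genotypes (across probe sets). With the replicate block 660 probe sets were higher and 462 lower, with 1 family higher and 1 lower. Of the named genes not called, 10 were called with the block. The main fit had no block, so its calls and the genes it did not call depend on treating the arrays as unpaired. Without the dense stretch on chromosome 5, 50 of 63 placed named genes remained higher and 19 of 20 lower. The alternatives for SOL2 could not be run, since no probe set was paired with it. Signal over background limits the low end: 13 calls had a lower-genotype mean no higher than the brightest bacterial control.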

Other observations

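The gene families were defined before any gene's change was computed but after the annotation had been seen, and all position tests except the next-door and near-SOL2 counts were chosen after the result was seen. Of 18 gene families, camera called none at an adjusted p under 0.05. The lowest adjusted p, 0.142, was shared by 6 AGAMOUS-like genes (5 above 0, median log2 0.15, unadjusted p = 0.0158) and 7 RALF-like peptide genes (6 below 0, median log2 -0.26, unadjusted p = 0.0150); SWEET transporters also had an unadjusted p under 0.05 (0.0430). With an estimated correlation both adjusted p were 0.828, and with fry 0.629 and 0.632, and neither tool called any family. Leaving out 1 array gave calls in each case, but the genotype left with 1 array was then assumed to vary like the other. Called members outside the largest changes, named after their values were seen, were 3. The cytochrome P450 gene CYP71B26 rose from 35.8 ± 19.2 to 285 ± 53.0 (adjusted p = 0.00934), the carboxypeptidase-like gene scpl42 from 27.1 ± 12.4 to 217 ± 29.2 (at least 6.2-fold against the highest bacterial control, adjusted p = 0.00782) and the peroxidase gene PRX52 from 35.2 ± 5.73 to 175 ± 30.9 (adjusted p = 0.0172), and for each of the 3 the signal of wild type replicate 2 lay under that control. Of 58 measured plastid-encoded genes none was called, and their median log2 difference was -0.04.

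The 90 placed genes at least 2-fold apart in every pair of arrays sat in clusters, with 10 next-door pairs and up to 13 in 200 consecutive tested genes against a median of 7 in random draws (permutation p = 0.0005). Signal shared by near-identical next-door copies does not account for all of this, since 86 pairs lay 6 to 50 tested genes apart against a mean of 48.8 (permutation p = 0.0001, the smallest possible). Probe mismatches in a mutant of another strain lower its signal. They therefore do not account for the genes higher in sol2, which made up 77.8% of the 90 (95% exact interval 67.8 to 85.9). That interval treats the genes as independent, so with clustered genes it is too narrow. Such mismatches stay open for the genes lower in sol2, which were not tested for clustering by themselves. A candidate explanation is that stretches of genome differ in strain between the sol2 and wild type plants; the 2338 tested genes within 20 tested genes of any of the 90 that did not themselves meet the criterion had a median absolute sol2 difference 1.19 times that of other genes (permutation p = 0.003 from 1000 shifted placements), while the ratio was 1.007 between the wild type arrays and 0.9795 between the sol2 arrays (p = 0.442 and 0.747). The strain of either genotype is not in the labels, and probe mismatches in the wild type, shared regulation of neighbouring genes and effects of the sol2 mutation itself stay open and untested. None of the 90 genes lay within 200 genes of SOL2, but random draws gave a mean of only 1.76. That count therefore cannot exclude a block around SOL2. Like the stretch densest in these genes, SOL2 lies on chromosome 5, though outside that stretch.

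The 4 arrays can be split into 2 pairs in 3 ways, too few for a share under 0.05. Only 1 of the 3, the real one, gave 170 calls, and the highest of the others gave 0. The split by replicate number had 1216 probe sets at an unadjusted p under 0.05, against 1215 for the real split, but only 7 that differed at least 2-fold in every pair, against 179.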
